A study of Mus musculus with 8 samples.

How the data were processed

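RNA was measured by sequencing in quadriceps muscle of 8 female mice aged 6 months, 4 labelled wild type (WT) and 4 labelled Mss51 knockout (KO), with 1 library per mouse and no pooling, per the labels. Per the labels, the muscles were frozen in cold isopentane, RNA was taken up in TRIzol, mRNA was enriched on oligo(dT) beads with ribosomal RNA removed by a Ribo-Zero kit, and paired-end reads of 150 bases were made to a stated 50 M read pairs (M for mega). The authors deposited 1 table per library with FPKM (fragments per kilobase of transcript per M mapped fragments), per the file headers. The labels name FastQC, TopHat2 2.1.1, Bowtie2 2.2.6, Cufflinks 2.2.1 and the genome build mm10, without the role of each. The annotation, the filters and the strand setting are not stated, so values of genes that overlap on opposite strands are uncertain.

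Each table held 46036 entries, of which 2379 had no gene name. Entries without a name carried 65.8% to 93.2% of the summed FPKM of a library, and they were left out of the comparison of genes. The 43239 distinct names included 344 on several entries, for which the entry with the highest mean FPKM was used. Names joined at 1 locus in the files were kept as they stand. The files hold no counts. Depth was estimated from 4073 genes with a single transcript, as FPKM times transcript length less 200 bases. The most crowded low value in a library, sought within preset bounds, was taken as 1 fragment. This gave a rough estimate of 41.2 to 57.6 M fragments per library, which those bounds limit. The labels give no batch, lane or date. Without counts, no counting interval and no limit for a value of 0 is given.

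The 11878 genes with a mean of at least 1 FPKM over the 8 libraries were tested, 185 of them listed at 0 in some library. FPKM were used as deposited, with no further scaling, as log2(FPKM + 0.5). The groups were compared as KO minus WT with limma 3.58.1 in R 4.3.3 (linear model of genotype alone, moderated variances with a mean trend, two-sided). The Benjamini-Hochberg adjustment ran over the genes tested, with a threshold of 0.05. Single values were compared with two-sided exact permutation tests over all 70 assignments of the 8 libraries, for which 0.0286 is the smallest p possible. Genes within 5 Mb of Mss51 were compared with the other tested genes by Fisher's exact test. That test takes genes as independent, though all come from the same 8 libraries and neighbours can share reads.

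Gene lists for 41 pathways and 17 cell types were fixed, and the 53 with at least 5 tested members were tested with camera of limma at a preset correlation between genes of 0.01, adjusted over the 53 lists. Beside it stand camera with an estimated correlation, fry, and an exact permutation test of each list's score, which is the mean over members of log2(FPKM + 0.5) minus the WT mean of each gene. Members were also adjusted over the list alone. The genes named were chosen by a rule: Mss51; up to 12 genes in each direction past the threshold whose groups do not overlap; genes with the smallest p up to a total of 20, named as not past the threshold; for each list past its threshold and each list on the theme of the series title, the 3 members with the smallest p; and 13 metabolic and fibre type genes. By this rule predicted genes and pseudogenes were named only where past the threshold. The part on flagged results names further pseudogenes, which the rule did not pick. The part on mitochondrially encoded genes names further genes for their high FPKM. The tests, lists, naming rule and first set of alternatives were chosen before the data were examined.

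Alternatives were other pseudocounts, filters, scalings, treatments of repeated names and of genes listed at 0, robust or weighted fits, the replicate number as a block, and each library left out in turn. Added after the data were seen were a scaling over genes above 0 in every library and the choice of repeated entries by median. The sum for that scaling also left out the gene Araf by name. Further such additions were chromosome 14 left out, removal of the trend with transcript length (lowess, span 0.3), and a model term for the libraries in which Tnnt3 is listed at 0. An estimated correlation without KO replicate 1 was added then too. The pipeline was tested on simulated data: of 200 genes changed by a factor of 1.5, 2 or 4 among the 11878, 32%, 76% and 97% were called, none with the wrong sign, beside 3, 11 and 7 false calls. When complex I was raised by a factor of 1.2 in them, the preset test called 2 lists, and the estimated correlation and fry called 1 each. The simulated genes varied independently of each other, while the real lists had a median estimated correlation of 0.283. The simulation therefore cannot show how the list tests behave with correlated members. Scores of lists were set against those of cell type markers by Pearson correlation after centring each group. Genes were placed with GENCODE M21, and pseudogene transcripts were aligned to its transcripts with blastn 2.17.0. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 did the rest.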

Results

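Quadriceps RNA from 8 female mice aged 6 months was compared between 4 libraries labelled wild type (WT) and 4 labelled Mss51 knockout (KO). The series title sets the question, which is how the loss of Mss51 bears on muscle metabolism and glucose homeostasis. The estimated depth was 41.2, 47.7, 49.2 and 57.6 M fragments (M for mega) in WT replicates 1 to 4 and 52.9, 42.0, 53.8 and 47.1 M in KO replicates 1 to 4. FPKM of 11878 genes were tested, and every log2 fold change is KO minus WT as the labels give the groups.

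Mss51, which encodes a mitochondrial protein of muscle named after a yeast factor for cytochrome oxidase translation, was not lower in the libraries labelled KO but higher in each of them. Its FPKM was 22.9, 37.0, 27.5 and 24.8 in the libraries labelled WT and 340, 201, 216 and 207 in those labelled KO. The means were 28.0 ± 6.28 FPKM in the WT group and 241 ± 66.1 FPKM in the KO group (SD, n = 4). The log2 fold change was 3.07 with an SE of 0.20 (exact permutation p = 0.0286, two-sided, the smallest possible; limma adjusted p = 0.000643). The gene (ENSMUSG00000021815) lies on chromosome 14 at 20482867 to 20496901 of mm10. The files give 1 value for its whole locus, so they do not show which exons were read. The targeted gene thus goes against what a knockout label leads to. All groups and directions here are those of the labels, which the files cannot settle.

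Besides Mss51, 5 genes differed between the groups, and all 6 were higher in the libraries labelled KO. The protein-coding ones were Oxnad1, an oxidoreductase with an NAD-binding domain, Psme1, a subunit of a proteasome activator, and Emc9, a subunit of the complex that inserts proteins into the endoplasmic reticulum membrane. Oxnad1 (chromosome 14, 32080545 to 32103218) stood at 39.6 ± 6.91 FPKM in the WT group and 87.4 ± 9.82 in the KO group (SD, n = 4). Its log2 fold change was 1.14 (SE 0.13, adjusted p = 0.0209). Psme1 rose from 35.3 ± 4.54 to 74.4 ± 3.54 FPKM (log2 fold change 1.07, SE 0.09, adjusted p = 0.00584). Emc9 rose from 34.5 ± 0.710 to 49.2 ± 0.915 FPKM (0.50, SE 0.05, adjusted p = 0.0171). These genes share 1 locus in the files (chromosome 14, 55578123 to 55585302) and meet on opposite strands, so with no strand setting given the split between them is uncertain. The antisense RNA Gm15935, placed in the files within the locus of Dusp13 (chromosome 14, 21733233 to 21800107), rose from 4.03 ± 1.61 to 23.7 ± 2.87 FPKM (2.48, SE 0.24, adjusted p = 0.00807), with the same limit of strand. Gm10704 (chromosome 3, 88575876 to 88588422), a processed pseudogene whose transcript is 98.6% identical to that of the chromosome 14 gene Rtraf (a comparison made after the values were seen), also rose. It stood at 0.0198 ± 0.0231 FPKM in the WT group and 3.58 ± 0.493 in the KO group (2.97, SE 0.16, adjusted p = 0.000348). That fitted value rests on the pseudocount and ran from 2.16 to 4.95 over the alternatives. No gene passed in the other direction in limma, where 328 genes were lower and 891 higher at an unadjusted p under 0.05. When FPKM were rescaled to an equal sum of named genes per library (TPM), Oxnad1 (0.93), Psme1 (0.86) and Emc9 (0.29) lost their calls.

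Several calls were lost when single libraries were left out, while the fold changes moved little. Gm15935 had an adjusted p of 0.0580 without KO replicate 4 (log2 fold change 2.41). Oxnad1 had adjusted p values of 0.103, 0.0901 and 0.0903 without WT replicates 1, 2 and 3, and of 0.0606, 0.0506 and 0.127 without KO replicates 2, 3 and 4 (log2 fold changes 1.08 to 1.19). Emc9 had 0.0601, 0.0857, 0.0582 and 0.0507 without WT replicates 1 to 4, and 0.0588 and 0.0739 without KO replicates 3 and 4 (log2 fold changes 0.49 to 0.52). The count of genes past the threshold was 125 without KO replicate 1, and all 6 were among them.

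**Figure D1:**
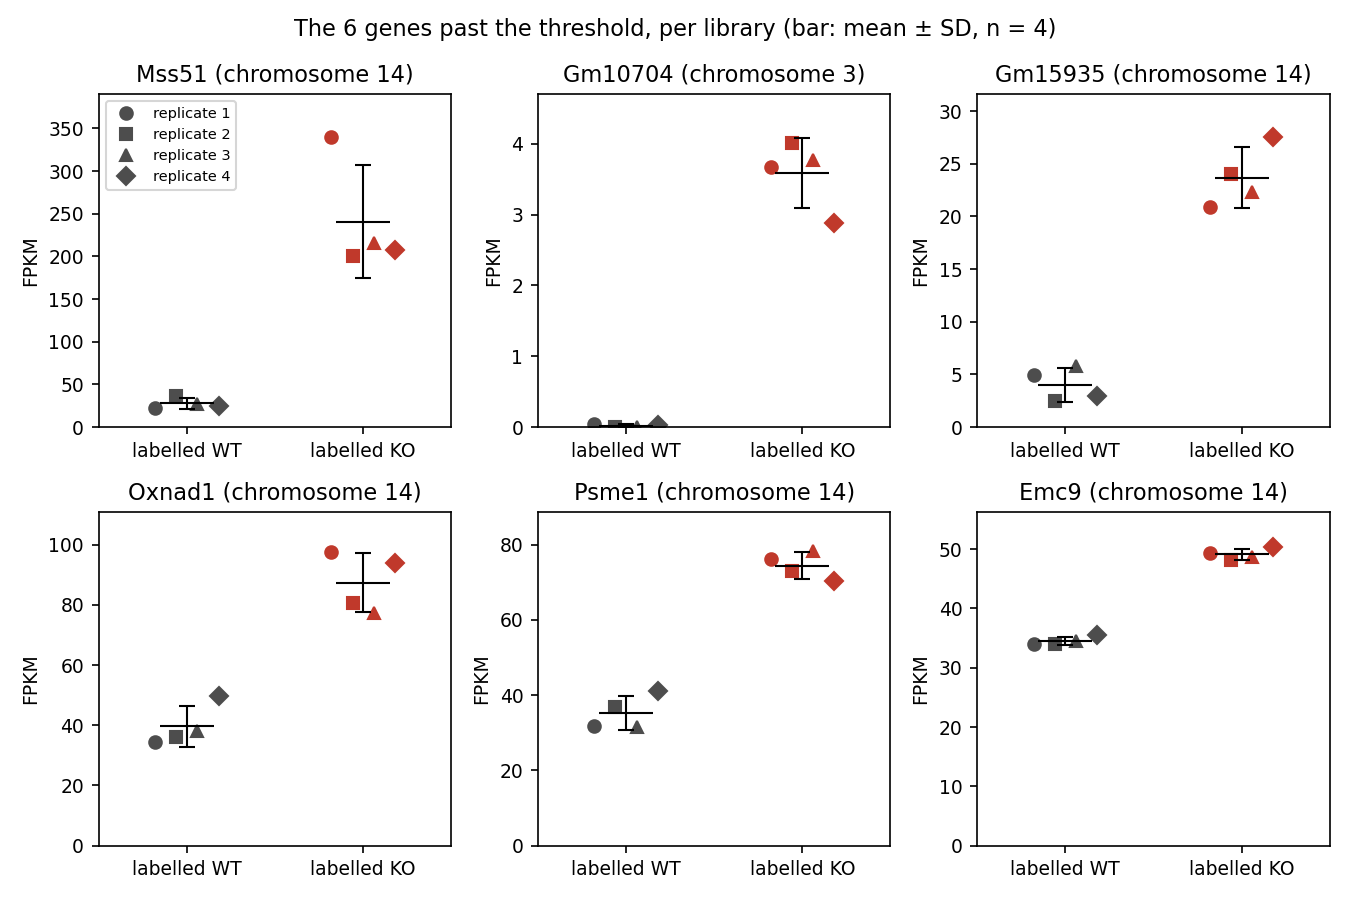
FPKM of the 6 genes past the threshold in each library, with points for replicates and bars for the mean ± SD (n = 4). In each gene the 4 libraries labelled KO lie above the 4 labelled WT, as for Mss51 with 201 to 340 against 22.9 to 37.0 FPKM.

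Genes around Mss51 and elsewhere on chromosome 14 made up most of the calls, 5 of 6. Within 5 Mb of Mss51, 1 of 51 other tested genes was called, Gm15935, against 4 of the other 11826 genes (Fisher exact p = 0.0213, two-sided). Without KO replicate 1 the number near Mss51 was 3, and without KO replicate 4 it was 0. The 14 genes next in order of p did not pass. They included 4 more of chromosome 14. Dusp13, a phosphatase of muscle, stood at 68.5 ± 5.82 against 108 ± 8.28 FPKM (log2 fold change 0.65, adjusted p = 0.0520). Asb14, an ankyrin repeat protein, stood at 71.6 ± 5.90 against 45.1 ± 3.84 FPKM (-0.66, adjusted p = 0.0520). The others were Abhd4, a lipase of N-acyl phospholipids (0.49, adjusted p = 0.173), and Osgep, a tRNA modification enzyme (0.42, adjusted p = 0.239). From other chromosomes came Vsig4, a complement receptor of macrophages (0.89, adjusted p = 0.185), and the imprinted RNA H19, joined with Mir675 (0.69, adjusted p = 0.194). From there also came Mterf2, a factor of mitochondrial transcription (0.42, adjusted p = 0.194), and Taf12, a subunit of the general transcription factor TFIID (0.63, adjusted p = 0.194). Erdr1 (1.71, adjusted p = 0.194), Plet1os (0.70, adjusted p = 0.250) and the complex I subunit Ndufb3 (0.41, adjusted p = 0.262) did not pass either. The other 3 were pseudogenes or predicted genes. Without KO replicate 1, Dusp13 (adjusted p = 0.0247), Asb14 (0.0134), Abhd4 (0.0303), H19 (0.00634), Erdr1 (0.0371), Plet1os (0.0381) and Ndufb3 (0.0445) passed. Erdr1 also passed without WT replicate 1 (0.0367), and Taf12 without KO replicate 4 (0.0274). With all 8 libraries, Dusp13 and Asb14 passed at a mean of at least 5 FPKM (0.0442 each), with robust variances (0.0366) and with genes listed at 0 left out (0.0380), Asb14 with array weights (0.0450) and Erdr1 after rescaling to TPM (0.0151).

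Nuclear genes of oxidative phosphorylation stood higher in the libraries labelled KO, by small amounts that depend on the scaling. All 37 complex I subunits, which pass electrons from NADH to ubiquinone, had a positive log2 fold change, with a median of 0.24 (camera adjusted p = 6.98e-17; adjusted p = 0.530 with an estimated correlation). So had the 14 tested subunits of complexes II and III with cytochrome c (median 0.28, adjusted p = 6.55e-09; adjusted p = 0.530 with an estimated correlation) and the 13 of complex IV (0.32, adjusted p = 3.96e-09; adjusted p = 0.530 with an estimated correlation). In the ATP synthase list 16 of 17 members were above 0 (0.26, adjusted p = 8.25e-08; adjusted p = 0.539 with an estimated correlation). With quantile normalization the medians of these 4 lists were 0.1169, 0.1384, 0.1618 and 0.0849 (-0.0147 for all genes), and after rescaling to TPM 0.0242, 0.0637, 0.1024 and 0.0477 (-0.1783 for all genes). No member passed over all genes tested, while adjusted over the list alone 16, 12, 11 and 7 members rose in these 4 lists. An example was Ndufb7 of complex I (275 ± 34.4 against 365 ± 30.4 FPKM, 0.42). In complexes II and III the examples were Sdhd (0.25), Uqcrc2 (0.28) and Uqcr11 (0.30), and in complex IV Cox7b (416 ± 51.8 against 579 ± 76.0 FPKM, 0.48), Cox7a2l (0.31) and Cox6b1 (1152 ± 133 against 1551 ± 202 FPKM, 0.43). In ATP synthase they were Atp5g1 (899 ± 89.7 against 1327 ± 219 FPKM, 0.55), Atp5f1 (0.35) and Atp5h (0.38). The scores of all 4 lists gave an exact permutation p of 0.0286. For complex I they were -0.16 to 0.10 in the WT group and 0.17 to 0.38 in the KO group. With the trend with transcript length removed, the medians of the 4 lists were 0.1335, 0.1839, 0.2217 and 0.2108. The exact permutation p of ATP synthase was then 0.0571. Without KO replicate 1, Uqcrc2 (adjusted p = 0.0471) and Atp5g1 (adjusted p = 0.0211) passed on their own.

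Across all 53 lists tested, 25 passed with the preset correlation, 16 higher and 9 lower, and 0 passed with an estimated correlation or by fry. At an unadjusted p under 0.05 the preset correlation, the estimated one and fry gave 31, 4 and 11 lists. Among the 25, the adjusted p with an estimated correlation ran from 0.530 to 0.751. The score of 8 lists had an exact permutation p under 0.05, with 0.189 as the smallest after adjustment. Of the 25 lists, 13 kept the call without each library and 12 lost it without some library. Rescaling to TPM moved the median of all genes from 0.02 to -0.18. All 16 lists called higher then stayed above that median, and all 9 called lower stayed below it. With that rescaling 10 of the 25 kept their calls, and among the oxidative phosphorylation lists complexes II and III (adjusted p = 0.0812) and ATP synthase (0.0742) lost theirs.

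**Figure D2:**
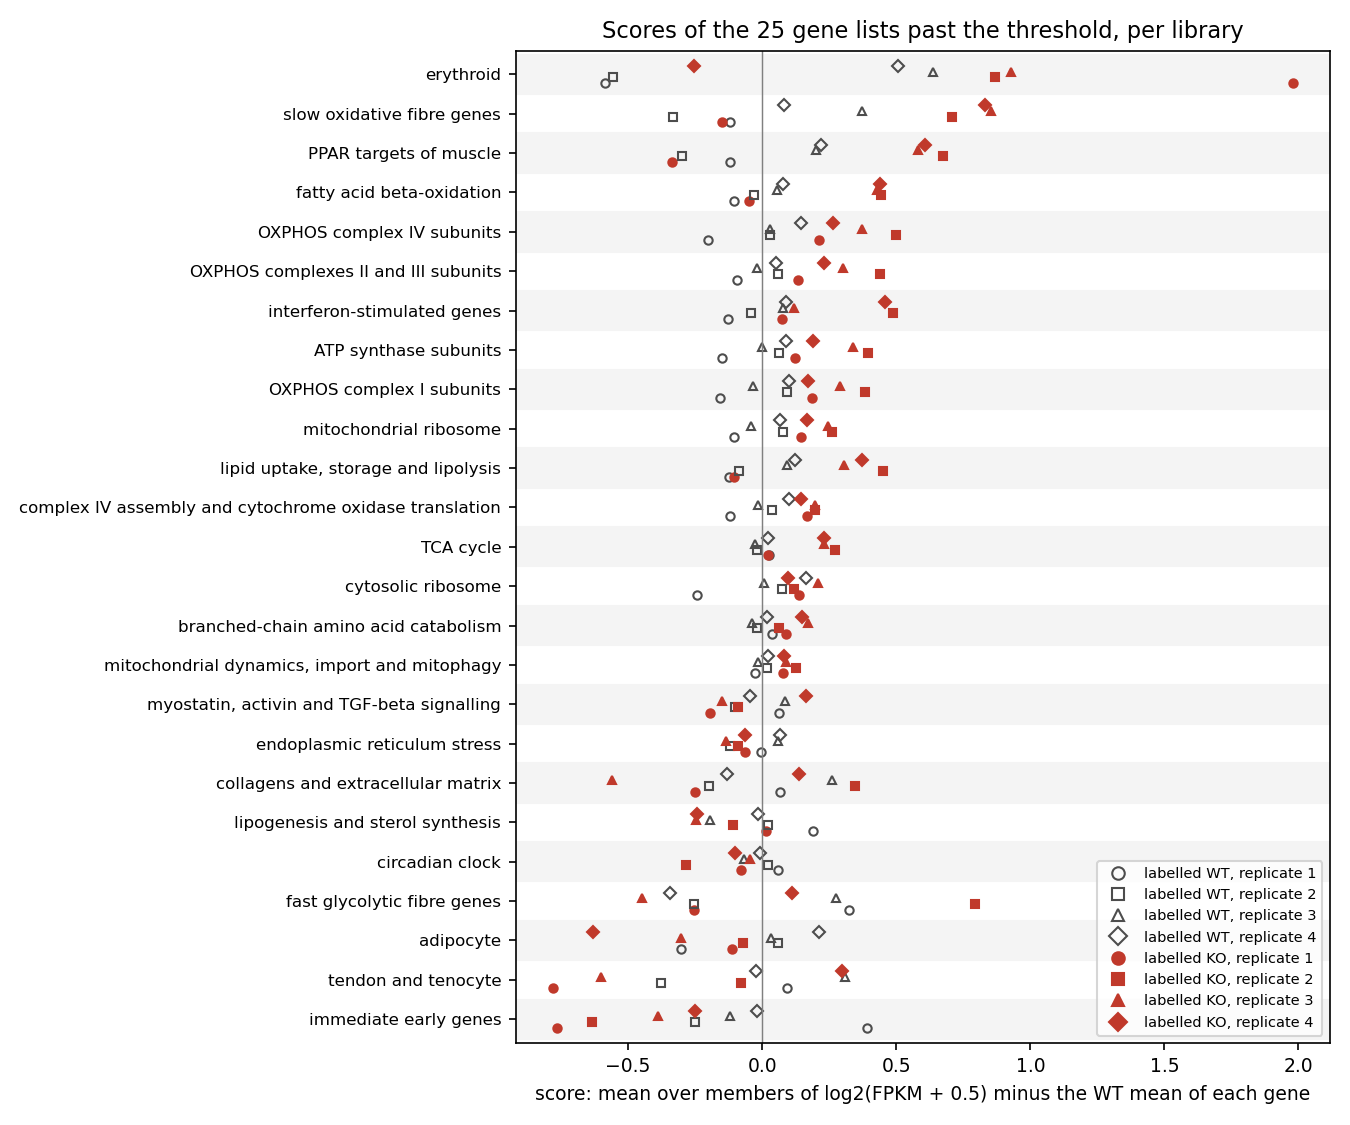
Scores of the 25 gene lists past the threshold in each library, as the mean over members of log2(FPKM + 0.5) minus the WT mean of each gene, with open points for WT and filled points for KO. Complex I runs from -0.16 to 0.10 in WT and from 0.17 to 0.38 in KO, while in slow oxidative fibre genes KO replicate 1 lies at -0.15 among the WT values.

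Lists of genes that build the mitochondrial machinery passed as higher with the preset correlation, with no member past the test. Mitochondrial ribosome proteins were above 0 in 39 of 40 (median 0.20, or -0.01 and 0.17 above the median of all genes after rescaling to TPM; adjusted p = 1.26e-11; adjusted p = 0.530 with an estimated correlation). Mrpl41 stood at 0.48, Mrpl12 at 0.41 and Mrps33 at 0.42, none past the test. After that rescaling the call was lost (adjusted p = 0.0575), as was that of the next list (0.2545). Factors for assembly of complex IV and cytochrome oxidase translation, the process of the yeast namesake of Mss51, were above 0 in 21 of 22 (0.17, or -0.03 and 0.15 above the median of all genes after rescaling; adjusted p = 0.000174; adjusted p = 0.530 with an estimated correlation). Its members Coa3 (0.31), Sco2 (0.33, a locus joined with Tymp) and Pet117 (0.29, joined with Csrp2bp) did not pass. The list of mitochondrial dynamics, import and mitophagy had 18 of 24 above 0 (0.08, or -0.13 and 0.04 above the median of all genes after rescaling, and -0.01 scaled over genes above 0 in every library; adjusted p = 0.0175; adjusted p = 0.530 with an estimated correlation). It lost its call without KO replicate 1 (adjusted p = 0.0552) and without KO replicate 3 (0.0506). It also lost it after rescaling to TPM (0.711), with quantile normalization (0.140), scaled over genes above 0 in every library (0.219) and with the trend with transcript length removed (0.166; median 0.02). Its members were Phb2, a prohibitin (0.31), Park2, a ubiquitin ligase of mitophagy (0.35), and Timm50, an import receptor (0.19, but -0.02 after rescaling). All 3 lists had an exact permutation p of 0.0286, which with the length trend removed was 0.0571 for the ribosome, 0.257 for dynamics and 0.0286 for assembly of complex IV (median 0.09). Adjusted over the list alone 0 members rose in any of them. Regulators of mitochondrial biogenesis did not pass as a list (median 0.06, adjusted p = 0.176), though they did at the preset correlation without WT replicate 1 (adjusted p = 0.0468). Ppargc1a, a coactivator of that program, had a log2 fold change of -0.01. It was 0.19 without KO replicate 1, 0.01 without WT replicate 3, 0.03 without WT replicate 4 and 0.06 without KO replicate 4.

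Lists of fuel oxidation stood higher as well. All 25 genes of fatty acid beta-oxidation were above 0 (median 0.32, adjusted p = 4.10e-11; adjusted p = 0.540 with an estimated correlation; exact permutation p = 0.114 for the score). After rescaling to TPM the median was 0.12 (-0.18 for all genes), with the call kept. Adjusted over the list alone, 8 of the 25 genes rose. The dehydrogenase Hadh stood at 94.6 ± 6.26 FPKM in the WT group and 125 ± 15.9 in the KO group (0.40), the isomerase Eci1 at 0.41 and the electron carrier Etfb, joined with Cldnd2, at 0.36. In the TCA cycle 17 of 18 genes were above 0 (0.14, or -0.07 and 0.11 above the median of all genes after rescaling to TPM; adjusted p = 3.23e-06; adjusted p = 0.539 with an estimated correlation; exact permutation p = 0.0571). Adjusted over the list alone, 7 rose. The mitochondrial isocitrate dehydrogenase Idh2 stood at 150 ± 13.2 against 288 ± 99.2 FPKM (0.86), Pdha1 of pyruvate dehydrogenase at 0.30, Idh3g at 0.19 (-0.02 after rescaling) and citrate synthase, Cs, at 0.14 (-0.08 after rescaling). After rescaling the TCA call was lost (adjusted p = 0.2545). Lipid uptake, storage and lipolysis had 18 of 22 above 0 (0.19, or -0.02 and 0.16 above the median of all genes after rescaling; adjusted p = 0.0116; adjusted p = 0.578 with an estimated correlation; exact permutation p = 0.143). It lost its call after rescaling (adjusted p = 0.0561) and without WT replicate 1 (median 0.12, adjusted p = 0.131) and KO replicate 2 (median 0.06, adjusted p = 0.102). In it the lipid droplet protein Plin3 stood at 0.62, the triglyceride synthesis enzyme Dgat2 at 0.69 and lipoprotein lipase, Lpl, at 139 ± 22.5 against 247 ± 73.2 FPKM (0.79). Adjusted over the list alone, 2 members rose. PPAR targets of muscle, of which 17 of 19 also sit in other lists, were above 0 in 18 of 19 (0.32, or 0.51 without KO replicate 1; adjusted p = 4.73e-05; adjusted p = 0.570 with an estimated correlation; exact permutation p = 0.229). The median of the PPAR targets was 0.12 after rescaling, with the call kept. Ech1, joined with Lgals4, stood at 0.34 and Acadm at 0.26. None of Ppara (0.19, -0.01 after rescaling and -0.05 without KO replicate 3), Cpt1b, joined with Chkb (0.23), Pdk4 (0.34, but -0.04 without WT replicate 2 and -0.05 without KO replicate 2) and Cd36 (0.38) passed. KO replicate 1 stood apart, with a beta-oxidation score of -0.05 and a PPAR score of -0.34. Without it Idh2 (adjusted p = 0.00647), Hadh (0.0241), Eci1 (0.0116), Plin3 (0.0116), Dgat2 (0.00647), Lpl (0.0180), Ech1 (0.0224) and Acadm (0.0443) passed.

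Slow oxidative fibre genes were higher as a list in the libraries labelled KO, with the score of KO replicate 1 (-0.15) inside the WT range. They had a median log2 fold change of 0.69, with 14 of 16 above 0 (adjusted p = 9.46e-05; adjusted p = 0.570 with an estimated correlation; exact permutation p = 0.114). In this list 0 members rose when adjusted over the list alone. Myoglobin, Mb, which stores oxygen, stood at 1736 ± 138 FPKM in the WT group and 3549 ± 1222 in the KO group (0.95), with 1838 in KO replicate 1. The slow myosin light chain Myl2 stood at 277 ± 65.2 against 629 ± 263 FPKM (1.08) and phospholamban, Pln, at 0.81. Without KO replicate 1 the list had a median of 0.90, and Mb (adjusted p = 0.00647), Myl2 (0.0218), Pln (0.0470) and Myh2 (0.00647), the myosin of fast oxidative fibres, passed. Myh2 stood at 130 ± 25.4 against 365 ± 165 FPKM (1.33, adjusted p = 0.353). Myh7, the slow myosin and itself a member of the list, joined with Myh6, did not rise with it, at -0.09 (0.05 without WT replicate 3). The fold change of Myh1 was 0.07. It was -0.14 after rescaling to TPM, -0.08 with quantile normalization and -0.01 rescaled over genes above 0 in every library. Without WT replicate 2 it was -0.05 and without KO replicate 2 -0.02. Of the FPKM of Myh1, Myh2 and Myh7 together, Myh2 made up 27.1 ± 1.19% in the WT group and 47.7 ± 13.5% in the KO group. The share of Myh1 was 66.2 ± 1.74% and 48.0 ± 12.5%, and that of Myh7 6.70 ± 0.972% and 4.34 ± 1.18% (exact permutation, adjusted p = 0.0857 each). Without KO replicate 1 the differences were 27.3, -24.4 and -2.90 percentage points (exact permutation, adjusted p = 0.0286 each, the smallest 4 against 3 libraries allow after adjustment). Myh4, the myosin of fast glycolytic fibres, is listed at 0 in all 8 libraries, so the shares leave it out and cover part of the fibres.

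The fast glycolytic list passed as lower, with 13 of 19 below 0 and a median of -0.14, although its mean was 0.05 (adjusted p = 0.00969; adjusted p = 0.570 with an estimated correlation). Adjusted over the list alone 1 member rose and 1 fell. Mybpc2, the fast myosin-binding protein, stood at 1175 ± 78.1 against 858 ± 132 FPKM (-0.46), the Z-disc protein Myoz3 at -0.40 and the regulator of glycolysis Pfkfb1 at 0.34. The call was lost without WT replicate 2 (adjusted p = 0.0926), KO replicate 2 (0.0537) and KO replicate 4 (0.165). The test turned upward after rescaling to TPM, where the median was -0.35 against -0.18 for all genes (adjusted p = 0.878). The list holds Tnnt3, listed at 0 in 4 libraries, and Atp2a1, listed at 0 in all but KO replicate 2, whose list score was 0.79, so the mean and the scores rest in part on these entries.

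**Figure D3:**
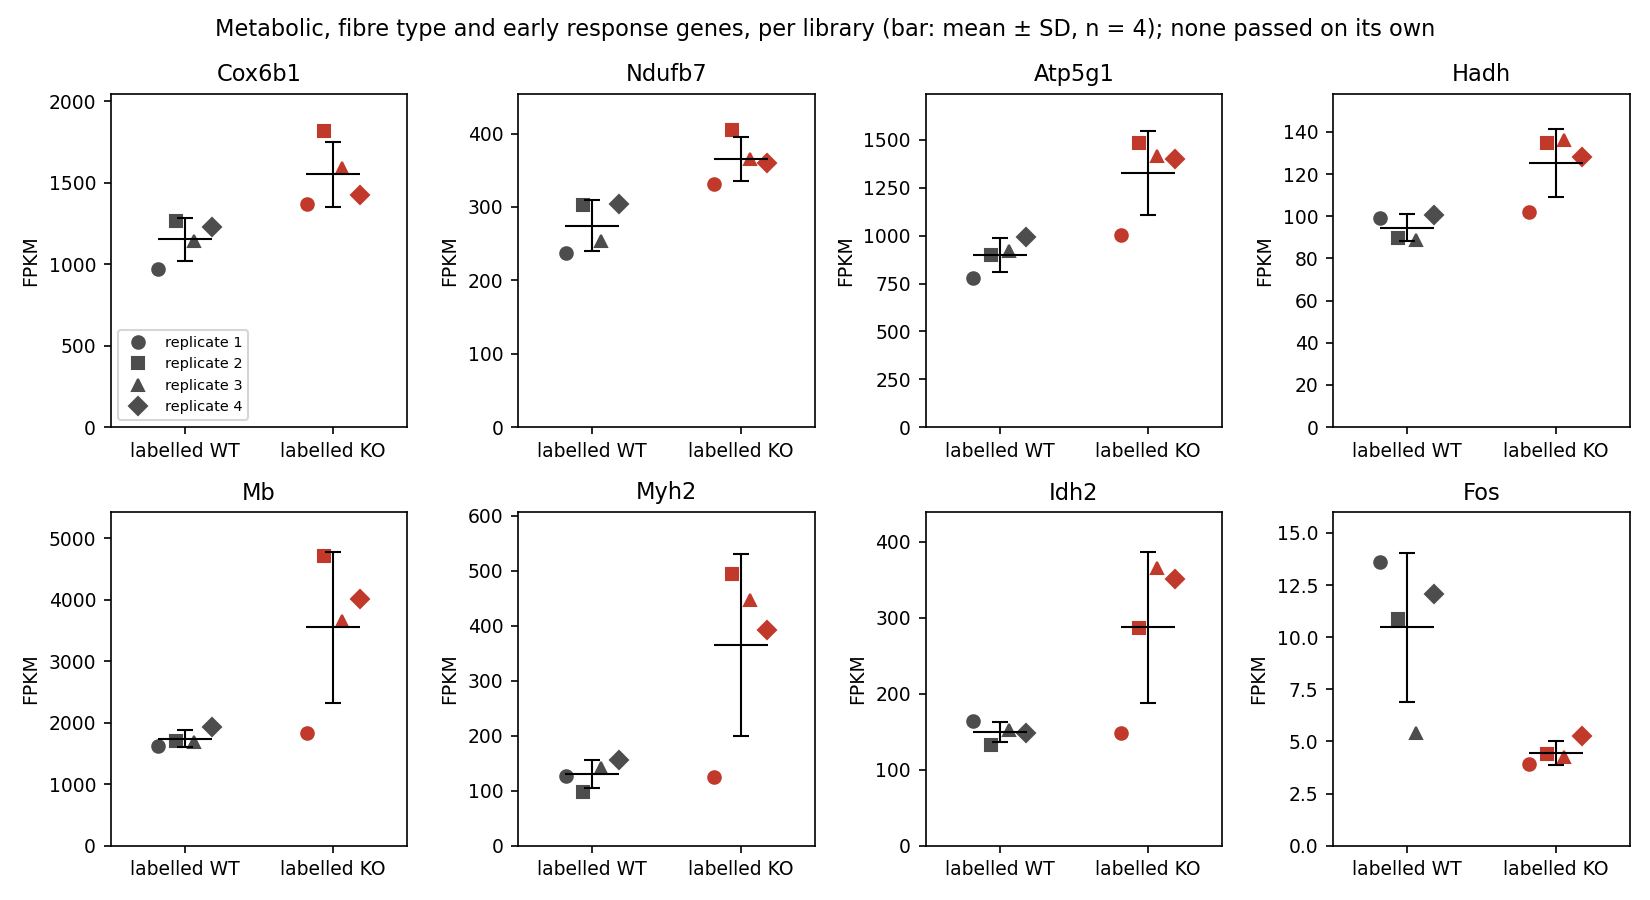
FPKM of 8 genes of oxidative metabolism, fibre type and early response in each library, with points for replicates and bars for the mean ± SD (n = 4). None passed on its own in the main test; Mb stands at 1838 FPKM in KO replicate 1 against a KO mean of 3549 and a WT mean of 1736.

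Glucose uptake and insulin signalling, the other theme of the title, did not pass as a list: 7 members were above and 16 below 0, with a median of -0.03 (adjusted p = 0.132; adjusted p = 0.608 with an estimated correlation). The insulin-responsive transporter Slc2a4 stood at 399.9 ± 39.1 FPKM in the WT group and 432 ± 32.2 in the KO group (0.11, but -0.10 after rescaling to TPM and -0.02 with quantile normalization). Hexokinase Hk2 stood at 0.10 (-0.12 after rescaling). The members with the smallest p were Grb14, an adaptor that binds the insulin receptor (11.9 ± 1.76 against 21.2 ± 6.58 FPKM, 0.76), the receptor substrate Irs1 (-0.40) and the kinase Pdpk1 (-0.23), none past the test. Grb14 passed without KO replicate 1 (adjusted p = 0.0147). Glycolysis had a median of -0.09 (adjusted p = 0.0783) and glycogen metabolism one of -0.01 (adjusted p = 0.0538). Glycolysis passed without WT replicate 3 (adjusted p = 0.0298) and KO replicate 1 (0.0185), and glycogen metabolism without WT replicate 4 (0.0225), KO replicate 1 (0.0229) and KO replicate 3 (0.0397). With an estimated correlation neither passed without KO replicate 1 (adjusted p = 0.348 and 0.391). With all 8 libraries, both passed at a mean of at least 5 FPKM (0.0296 and 0.0116) and with quantile normalization (0.00545 and 0.0120), glycolysis with the trend with transcript length removed (median -0.18, 0.0202) and with the Tnnt3 term (0.0391), and glycogen metabolism with the replicate block (0.0340), with genes listed at 0 left out (0.0479) and with chromosome 14 left out (0.0485).

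Immediate early genes, which respond within minutes to activity and handling, were lower in the libraries labelled KO in 19 of 20 members (median -0.46, adjusted p = 6.55e-09; adjusted p = 0.530 with an estimated correlation; exact permutation p = 0.0571). Fos stood at 10.5 ± 3.57 FPKM in the WT group and 4.47 ± 0.575 in the KO group (-1.08), Atf3 at -0.69 and Nr4a3 at -1.38. The list scores were -0.25 to 0.39 in the WT group, highest in replicate 1, and -0.77 to -0.25 in the KO group. The median was -0.28 without WT replicate 1 and -0.67 after rescaling to TPM. In the list 3 members fell when adjusted over the list alone. Fos passed over all genes without WT replicate 3 (adjusted p = 0.0158), and Fos (0.0408) and Nr4a3 (0.00271) after rescaling. Circadian clock genes were below 0 in 16 of 19 (-0.13, adjusted p = 0.0193; adjusted p = 0.540 with an estimated correlation). Cry2 stood at -0.31, Bhlhe41 at -0.38 and Rora at -0.15. That call was lost without WT replicate 1 (median -0.09, adjusted p = 0.0582), WT replicate 2 (-0.13, 0.0511), KO replicate 2 (-0.05, 0.219) and KO replicate 4 (-0.09, 0.0858). It was also lost after rescaling to TPM (0.122), scaled over genes above 0 in every library (0.0703) and with the trend with transcript length removed (0.0634).

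Signalling, stress and matrix lists were lower by small amounts. Myostatin, activin and TGF-beta signalling had 20 of 28 below 0 (median -0.08, adjusted p = 0.0126; adjusted p = 0.570 with an estimated correlation). The growth factor Tgfb2 stood at 14.3 ± 1.07 against 9.60 ± 1.73 FPKM (-0.56), Gdf11 at -0.30 and Smad4 at -0.15. Mstn, the brake on muscle growth, stood at -0.06 (0.05 without WT replicate 3 and 0.11 without KO replicate 2). Adjusted over the list alone 1 member fell, and the call was lost without KO replicate 1 (median -0.05, adjusted p = 0.140), after rescaling to TPM (0.2545) and with the length trend removed (0.0812). Endoplasmic reticulum stress had 18 of 21 below 0 (-0.08, adjusted p = 0.00756; adjusted p = 0.543 with an estimated correlation). The oxidase Ero1l stood at -0.57, Xbp1 at -0.21 and Dnajc3 at -0.15 (Ero1l and Dnajc3 lie on chromosome 14), and the list lost its call without WT replicate 4 (adjusted p = 0.0573) and after rescaling (0.256). Lipogenesis and sterol synthesis had 17 of 21 below 0 (-0.13, adjusted p = 0.0126; adjusted p = 0.543 with an estimated correlation). The desaturases Scd1 and Scd2 stood at -0.71 and -0.39 and Sqle of sterol synthesis at -0.35. Within the groups Scd1 followed the score of the adipocyte markers (Pearson r = 0.75 over 8 libraries) and the list did not (-0.05), a comparison made after the values were seen. This list lost its call without WT replicate 1 (median -0.02, adjusted p = 0.144) and KO replicate 4 (median -0.09, adjusted p = 0.0758), and after rescaling (0.0742). Collagens and extracellular matrix had 23 of 31 below 0 (-0.12, adjusted p = 0.0363; adjusted p = 0.751 with an estimated correlation). Timp2 stood at -0.27, Lox at -0.32 and Postn at 0.49. Within the groups the matrix score, without shared members, followed those of fibroblast (r = 0.93) and tendon markers (0.79), also compared after the values were seen. The matrix call was lost without WT replicate 1 (median -0.07, adjusted p = 0.102), WT replicate 3 (-0.03, 0.341) and KO replicate 1 (-0.08, 0.222), and without KO replicate 3 the median was 0.06 (adjusted p = 0.850). It was also lost after rescaling (0.223), with quantile normalization (0.0696), array weights (0.0518), scaling over genes above 0 in every library (0.176) and the length trend removed (0.204).

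Of the 12 lists of cell type markers tested, 3 passed with the preset correlation, those of adipocytes, tendon and erythroid cells. Adipocyte markers were below 0 in 9 of 14 (median -0.17, adjusted p = 0.0172; adjusted p = 0.570 with an estimated correlation). Leptin, Lep, stood at 3.36 ± 0.955 against 1.01 ± 1.19 FPKM (-1.59), the lipid droplet protein Plin1 at -0.73 and the hormone Adipoq at -0.51. The adipocyte call was lost without WT replicate 2 (median -0.15, adjusted p = 0.0599), WT replicate 4 (-0.12, 0.143) and KO replicate 4 (-0.10, 0.356), at a mean of at least 5 FPKM (-0.09, 0.0710) and scaled over genes above 0 in every library (-0.26, 0.0628). Lep passed on its own without KO replicate 1 (adjusted p = 0.0105) and after rescaling to TPM (0.00172). Tendon markers were below 0 in 8 of 9 (-0.18, adjusted p = 0.0235; adjusted p = 0.601 with an estimated correlation). The matrix proteins Comp and Fmod stood at -0.71 and -0.72 and Tnmd at -0.61. These markers lost their call without WT replicate 3 (median -0.05, adjusted p = 0.118) and KO replicate 1 (median -0.07, adjusted p = 0.2997), and also at a mean of at least 5 FPKM (0.0628), with quantile normalization (0.0504), scaled over genes above 0 (0.1135) and with the length trend removed (0.0534). Erythroid markers were above 0 in 6 of 6 (0.87, adjusted p = 0.00886; adjusted p = 0.570 with an estimated correlation). The haemoglobin gene Hbb-bs stood at 367 ± 162 against 746 ± 391 FPKM (0.96) and Hbb-bt at 0.99. The erythroid score was 1.98 in KO replicate 1 and -0.25 in KO replicate 4, and without KO replicate 1 the median was 0.52 (adjusted p = 0.174). None of the members named passed in the main test. Macrophage (median 0.11, adjusted p = 0.612), satellite cell (-0.06, 0.427), mast cell (0.10, 0.688), spindle fibre (-0.09, 0.540) and Schwann cell markers (0.01, 0.880) did not pass.

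Interferon-stimulated genes and ribosomal proteins were higher. Of the interferon-stimulated genes 28 of 29 were above 0 (median 0.28, adjusted p = 1.39e-05; adjusted p = 0.548 with an estimated correlation; exact permutation p = 0.0857). After rescaling to TPM the median of this list was 0.08 (-0.18 for all genes), with the call kept. The antiviral genes Rsad2 and Bst2 stood at 2.12 ± 0.574 against 4.00 ± 1.15 FPKM (0.78) and at 0.60, and the antigen-presenting H2-K1 at 0.27. Cytosolic ribosome proteins were above 0 in 48 of 50 (0.14, or -0.08 and 0.10 above the median of all genes after rescaling to TPM; adjusted p = 1.12e-05; adjusted p = 0.608 with an estimated correlation). Rps13 stood at 0.35, Rps24, a gene of chromosome 14, at 0.32 and Rpl22 at 0.26. The ribosome call was lost after rescaling (adjusted p = 0.2545), with quantile normalization (median -0.0015, adjusted p = 0.782) and after removal of the trend with transcript length (0.02, adjusted p = 0.437), an alternative chosen after seeing the data. Branched-chain amino acid catabolism was above 0 in 19 of 22 (0.09, or -0.12 and 0.06 above the median of all genes after rescaling; adjusted p = 0.00630; adjusted p = 0.530 with an estimated correlation; exact permutation p = 0.0286, or 0.0571 with the length trend removed). The transaminase Bcat2 stood at 0.20 (-0.01 after rescaling), Pcca, a gene of chromosome 14, at 0.52 and Hibch at 0.26. Without KO replicate 3 the adjusted p of the list was 0.0503, after rescaling 0.536 and scaled over genes above 0 in every library 0.0615. In these 3 lists 0 members rose when adjusted over the list alone.

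Genes encoded in the mitochondrial genome did not pass as a list (7 tested, median 0.14, mean -0.97, adjusted p = 0.738). The median was -0.07 after rescaling to TPM and -0.06 with quantile normalization. The complex I subunit mt-Nd1 stood at 28720 ± 1218 against 33730 ± 2402 FPKM (0.23, exact permutation p = 0.0286, not adjusted; -0.06 with quantile normalization). Another, mt-Nd2, had a log2 fold change of 0.15 (-0.06 after rescaling and -0.07 with quantile normalization). The mean is carried by genes listed at 0 in some libraries labelled KO, mt-Co2 in 2 (-4.01) and mt-Cytb in 1, whose fitted values rest on the pseudocount. After rescaling to TPM the list passed (adjusted p = 2.22e-12), and so did mt-Co2 (lower, adjusted p = 2.90e-24), neither in another scaling. As FPKM, mt-Co2 stood at 143 in KO replicates 1 and 4 and at 129 to 149 in the WT group (exact permutation p = 0.343, not adjusted). Its adjusted p after rescaling therefore does not measure the spread between libraries. The genes mt-Co1, mt-Co3 and mt-Nd4 are listed at 0 in all 8, so the list covers part of the genome. Mitochondrially encoded genes made up 11.7 ± 2.55% of the summed FPKM of named genes in the WT group and 11.01 ± 2.98% in the KO group (exact permutation p = 0.657). Entries without a name are outside this sum. The difference was 0.14 percentage points without WT replicate 1 and 0.78 without KO replicate 4. By mean FPKM the highest named genes were Atg7 (115200) and the predicted gene Gm22953 (58700), above mt-Nd1 (31220). The share of the 10 highest genes was 53.2% in WT replicate 3, 63.1% in KO replicate 4 and at most 20.2% in each other library. The 10 highest genes made up 28.3 ± 16.6% of the summed FPKM of named genes in the WT group and 29.4 ± 22.6% in the KO group (exact permutation p = 0.943). That difference was -1.63, -1.59 and -1.77 points without WT replicates 1, 2 and 4 and -10.1 without KO replicate 4.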

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

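The tests of explanations in this part were all chosen after the results they bear on were seen.

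Genes of chromosome 14 stood apart between the groups: 47 of 411 (11.44%) had groups that do not overlap, against 2.857% by chance and 7.45% on chromosome 19, the next highest. That share argues against a response to the loss of Mss51 with no regard to where a gene lies as the whole cause. Of the genes within 20 Mb of Mss51 11.76% stood apart, of those 20 to 40 Mb away 18.94% (25 of 132; Fisher exact p = 3.65e-08 against other chromosomes, 0.127 against those within 20 Mb) and of those farther off 3.52%, against 5.28% on other chromosomes. Fisher's test takes genes as independent, while all rest on the same libraries, so its p can overstate the evidence. Of the 4 processed pseudogenes under 0.5 FPKM in each library labelled WT and at 0.5 or more in each labelled KO, 75% are closest to genes of chromosome 14. That chromosome holds 4.11% of protein-coding genes. AC115117.1 is closest to Osgep (97.9% identical), Gm3375 to Psmb5 (98.9%) and Gm10704 to Rtraf (98.6%), all singled out after their values were seen. Gm11971 is closest to Sumo2 of chromosome 11. With the groups exchanged, 0 processed pseudogenes met these limits. The 3 copies of chromosome 14 genes lie on chromosomes 18, 7 and 3, so distance along chromosome 14 does not apply to them. Sequence of another strain along chromosome 14 in 1 group, through which reads align to such copies, and an effect of the targeted locus that falls with distance cannot be told apart, since no strain is given in the labels and the shares within 20 Mb and 20 to 40 Mb away did not differ past the test; a response of single genes stays untested.

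Mss51 had the higher FPKM in the libraries labelled KO. A single mislabelled library is argued against, since the lowest value labelled KO was 5.43 times the highest labelled WT. An exchange of the labels of both groups as a whole may account for it, with 37.0 FPKM as the highest value labelled WT, and so may RNA made from the targeted allele, with a mean of 240.9 FPKM labelled KO. These cannot be told apart, because the files give 1 value per gene and none per exon.

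Oxidative phosphorylation lists were higher in the libraries labelled KO. Lower FPKM for longer transcripts in that group could raise short genes, and log2 fold changes fell with transcript length (Spearman correlation -0.25, 11451 genes). After the trend was removed from each library the median of complex I was 0.1335 (0.2384 before), and all 4 lists stayed past the preset test. That test presets a correlation of 0.01 where 0.51 to 0.65 was estimated, so it cannot decide whether the trend is the whole cause. With an estimated correlation the lists had not passed before the removal (adjusted p = 0.530 to 0.539). The exact permutation p of the score, not adjusted, stayed at 0.0286 for complex I, complexes II and III and complex IV. For ATP synthase it went from 0.0286 to 0.0571. Fibre type makeup of the muscle pieces, which a biological change or the site of sampling could give, stays open. KO replicate 1 was the only library labelled KO with a slow fibre score within the WT range. Its complex I score was 0.1861, above each WT library. With the length trend removed it was 0.0734, against 0.059 as the highest in WT. In that setting complexes II and III had 0.038 against 0.0374 and complex IV 0.0628 against 0.0403. ATP synthase had 0.0378, below the highest WT score of 0.0439. In any case 1 library decides nothing.

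Of 339 groups of 4 libraries examined for a value far from the other 3, 21 (6.19%) had one, where chance gives about 1 in 20. In KO replicate 1 these were Mss51 (340 FPKM), Mrpl41 (59.5), Rps13 (648), Lep (2.79), the scores of the TCA cycle (0.0231), beta-oxidation (-0.0509), PPAR targets (-0.3364), slow oxidative fibre genes (-0.1481), sarcomere genes (0.0538) and heat shock genes (-0.1141), and the myosin shares of Myh1 (66.6%) and Myh2 (27.5%). In KO replicate 3 it was the glycolysis score (0.0333). In KO replicate 4 they were Fmod (64.4 FPKM), the mitochondrially encoded share (6.58%) and the share of the 10 highest genes (63.1%). Among the WT libraries they were Rps13 (486 FPKM), Slc2a4 (458 FPKM) and the Schwann cell score (-0.1381) in replicate 1, and the Myh7 share (8.15%) and the share of the 10 highest genes (53.2%) in replicate 3. Signal at entries without a gene name, outside the comparison of genes, was at least 383 FPKM in each library labelled KO at the pseudogene AC115117.1 (chromosome 18) and 0 in each labelled WT, and at least 17.4 FPKM at Gm3375 (chromosome 7) against at most 0.405.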

How the results depend on the processing

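All alternatives here were planned except the scaling over genes above 0, the choice of entries by median, chromosome 14 left out, the length trend, the Tnnt3 term and the estimated correlation without KO replicate 1, which were chosen after seeing the data. Mss51 was higher in each alternative that tested it and kept its call in 24 of 25, with log2 fold changes of 2.86 to 3.21. Gm10704 kept its call in 23 of 24, Gm15935 and Psme1 in 23 of 25, Oxnad1 in 15 and Emc9 in 14. Complex I kept its call in 26 of 29 alternatives, losing it with an estimated correlation (also without KO replicate 1) and fry. Unless the construction of an alternative shows it, the cause was not tested. The files hold no counts, so the limit that depth sets on low genes is unknown.

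With the replicate number as a block, 0 genes passed, 0 higher and 0 near Mss51 (adjusted p of Mss51 0.0530; range over its alternatives 1.85e-08 to 0.0530), while 26 lists passed; the numbers pair no samples by the labels, and residuals of equal numbers correlated at -0.08 to 0.01. Rescaling to TPM gave 114 genes, 60 higher and 54 lower (3 of the 6 kept), 3 near Mss51, and 13 lists, 8 higher and 5 lower (10 kept). Among the genes passing there was mt-Co2, whose FPKM in KO replicates 1 and 4 lay in the WT range. An adjusted p of this rescaling thus need not measure the spread between libraries. Lower genes numbered 1 with a mean of at least 5 FPKM, robust variances, array weights, genes listed at 0 left out, and an adjusted p under 0.1; with the first 2 and with genes at 0 left out, genes near Mss51 numbered 2. With chromosome 14 left out, 1 gene passed, 1 higher, since 5 of 6 lie there. Scaled over genes above 0 in every library, 5 lists were lower. An estimated correlation gave 0 lists, 0 higher and 0 lower, as did fry (0, 0, 0) and an estimated correlation without KO replicate 1 (0, 0, 0).

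Leaving out 1 library gave 4 to 125 genes, 4 to 113 higher and 0 to 12 lower, with 0 to 3 near Mss51. The most genes, and 12 lower and 3 near, came without KO replicate 1; without KO replicate 2 there were 3 lower, without WT replicate 3 there was 1, and 0 near without KO replicate 4. Differences ran from -24.4 to -15.9 for the Myh1 share, 18.0 to 27.3 for Myh2 and -2.90 to -1.88 for Myh7 (past the test without KO replicate 1 only), -1.89 to 0.776 for the mitochondrial share and -10.1 to 9.42 for the 10 highest genes. As FPKM, the Myh1 difference was 15.5. Log2 fold changes ran from -0.0528 to 0.1399 for gene Myh1, -0.2336 to 0.0453 for gene Myh6,Myh7, -0.1973 to 0.1855 for gene Ppargc1a, -0.0522 to 0.4636 for gene Ppara, -0.0477 to 0.9617 for gene Pdk4 and -0.2388 to 0.1056 for gene Mstn. The median of the list collagens and extracellular matrix ran from -0.2698 to 0.0572.

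Directions turned after rescaling to TPM, whose sum rests on a few very high entries, for Idh3g (-0.0237), Timm50 (-0.0174), Bcat2 (-0.0095), mt-Nd2 (-0.0621), Myh1 (-0.1417), Ppara (-0.0060), Slc2a4 (-0.1011), Hk2 (-0.1153), Cs (-0.0762), the mitochondrially encoded list (-0.0688) and the test of the fast glycolytic list (median -0.3514). Of the 16 lists called higher, 7 also had a median below 0 after that rescaling, while all 16 stayed above the median of all genes (-0.1783). Quantile normalization turned mt-Nd1 (-0.0614), mt-Nd2 (-0.0659), Myh1 (-0.0807), Slc2a4 (-0.0232) and the mitochondrially encoded list (-0.0614). It also took the median of the cytosolic ribosome list to -0.0015 (-0.0147 for all genes). Scaled over genes above 0, Myh1 turned (-0.0123), and the median of the mitochondrial dynamics list was -0.006 (-0.0618 for all genes). Ppargc1a turned with array weights (0.0392) and without the length trend (0.0166).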

Other observations

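Some tests in this part were chosen only after results were seen. These are the counts of genes without KO replicate 1, the comparison with Tnnt3 and its model term, and chromosome 14 left out. Removal of the length trend and the estimated correlation without KO replicate 1 also belong to them. Over other splits, the counts of genes and of lists past the threshold were planned. Counts over splits of genes that do not overlap and of unadjusted p were not part of the plan.

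Without KO replicate 1, the library whose slow fibre, beta-oxidation and PPAR scores stood apart from the other 3 labelled KO, 113 genes were higher and 12 lower in the libraries labelled KO, 11 of them on chromosome 14. Among them, picked by hand after their values were seen and not tested as a set, were the heart-type lactate dehydrogenase Ldhb (log2 fold change 1.64, adjusted p = 0.00360), the ketone body enzymes Bdh1 (2.37, adjusted p = 0.00647) and Oxct1 (0.64, adjusted p = 0.0133), the mitochondrial creatine kinase Ckmt2 (1.17, adjusted p = 0.0108), the fatty acid carrier Fabp3 (1.32, adjusted p = 0.0158) and Fndc5, the precursor of irisin (1.03, adjusted p = 0.00360). Lower were the muscle-secreted Ostn (-0.90, adjusted p = 0.0105), the lactate exporter Slc16a3 (-0.85, adjusted p = 0.0304) and Phka1, a subunit of phosphorylase kinase (-0.52, adjusted p = 0.0266). These calls rest on leaving out a library for its values, and with all 8 libraries none of these 9 genes passed.

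Several further lists did not pass with all 8 libraries. Among cell types these were pericyte and smooth muscle (median -0.10, adjusted p = 0.0504), fibroblast (-0.11, 0.0783), endothelial cell (0.18, 0.120) and neutrophil markers (-0.13, 0.393). Among pathways these were cytosolic heat shock (0.08, 0.0606), proteasome (0.07, 0.0783), angiogenesis (0.15, 0.120), myogenesis (-0.12, 0.176), glucocorticoid targets (-0.07, 0.183), thermogenesis and calcium cycling (-0.0036, 0.287), antioxidant defence (0.10, 0.287), denervation (0.06, 0.439), myokines (0.09, 0.470), sarcomere (0.07, 0.592), inflammation (-0.05, 0.592), atrophy and autophagy (0.08, 0.738), the integrated stress response (0.13, 0.738) and BMP and Id genes (0.05, 0.930). Leaving out 1 library took some past the threshold. Pericyte markers passed without WT replicate 1 (adjusted p = 0.00624) and KO replicates 2 (0.0178) and 4 (0.0160), fibroblast markers without WT replicate 1 (0.0472) and KO replicates 2 (0.0110) and 4 (0.00544), endothelial markers without WT replicate 3 (0.00914) and KO replicates 1 (0.00377) and 3 (0.0421), and neutrophil markers without KO replicate 4 (0.0107). Heat shock genes passed without WT replicates 1 (0.0460) and 3 (0.0169) and KO replicate 1 (0.00133), the proteasome without WT replicate 2 (0.000488) and KO replicates 2 (0.0454) and 4 (0.00955), angiogenesis without KO replicate 1 (0.00730), and glucocorticoid targets without WT replicate 2 (0.00869) and KO replicate 3 (0.0245). With all 8 libraries, some passed in other alternatives: pericyte and smooth muscle markers in 7, among them no filter (0.0296), median-of-ratios scaling (0.0441) and quantile normalization (0.0247), fibroblast markers with quantile normalization (0.0383) and the Tnnt3 term (0.0421), heat shock genes with no filter (0.0377), array weights (0.0207) and the Tnnt3 term (0.0422), the proteasome with no filter (0.0258), chromosome 14 left out (0.0327) and the Tnnt3 term (0.0333), the sarcomere (0.0108) and neutrophil markers (0.0371) after rescaling to TPM, and angiogenesis (0.0468) and endothelial markers (0.0398) with the trend with transcript length removed. These are calls at the preset correlation; with an estimated one 0 lists passed without KO replicate 1, the only library left out for which it was tried. Brown adipocyte, cartilage and bone, T and NK cell, B and plasma cell, and epithelial markers had 2, 3, 1, 3 and 1 tested members and were not tested.

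The labelled groups gave 6 genes past the threshold, and of the 35 splits of the 8 libraries into 4 and 4 this was the only 1 with as many (highest other 4). That is under 5% of the splits and the smallest share that 35 splits allow. The 6 genes are Mss51 and others of which most lie on its chromosome (5 of 6 on chromosome 14), so they are not independent calls. They gave 25 lists, and 2 of the 35 splits, the labelled one included, gave as many (highest other 26), so chance cannot be excluded for the number of lists. The groups of 653 genes (5.50%) did not overlap, where chance gives 2.857%, but 3 of the 35 splits, the labelled one included, gave as many, so chance cannot be excluded for this count. One of them, WT replicates 1, 2 and 4 with KO replicate 1 against the rest, gave 795. The largest was WT replicates 1 and 3 with KO replicates 2 and 4, against WT replicates 2 and 4 with KO replicates 1 and 3, which gave 1209 genes that do not overlap and 1971 at an unadjusted p under 0.05, against 653 and 1219 for the labelled groups, with 4 genes past the threshold. Its sides have opposite signs on the first principal component (20.3% of the variance), and Tnnt3 is listed at 0 in each library of the latter side and at 7955 to 8888 FPKM in the former. The sides also differ in the Spearman correlation of each library's deviations from the WT mean with transcript length, compared after the split was seen. It was 0.25, 0.13, -0.16 and -0.03 on the former side and -0.19, -0.20, -0.29 and -0.21 on the latter. These values, from the same data that picked the split, point to a structure of the libraries that crosses the labelled groups evenly and that no label explains. Whether transcript length accounts for it was not tested. With Tnnt3 listed at 0 as a model term, 30 lists passed, all 25 among them, and the same 6 genes.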
